A study of Mus musculus with 28 samples.

How the data were processed

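Gene expression was measured in cortical brain tissue of 28 mice, 7 in each of 4 groups formed by genotype (wild type, WT, or Rbm5 knockout, KO) and by procedure (sham or controlled cortical impact, CCI). Per the labels' protocols, sham animals received anaesthesia alone, injured animals received a craniotomy and an impact, tissue was taken 48 h later after perfusion with saline, total RNA was extracted with Trizol, and 100 ng was labelled with biotin for the MTA 1.0 array. The deposited table holds log2 signal, read from the values themselves, which lay between 2.214 and 19.93. The array medians lay between 5.79 and 5.90, which is close but does not establish a common scale. Whether and how the authors normalized the values, and with which software, is not given in the sources used here. No further normalization was applied for the values reported.

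The table held 72688 transcript clusters, of which 6732 were controls (31 AFFX, 155 ERCC, 5222 negative and 1324 positive) and were left out. The remaining 65956 were tested. Gene names came from the annotation supplied with the files, which listed 32750 of the tested transcript clusters. Of these, 30468 carried 1 gene symbol, 612 carried older names of 1 gene, and 1670 listed several genes and were not named. No gene was listed for 33206. Names were updated for 827 through the gene identifier in the RefSeq annotation of GRCm38.p6. Where the chromosome in the cluster identifier could be compared with that of the gene (30591), 100 differed and were left unnamed, a rule added after the annotation was examined. A gene with several transcript clusters, as 292 genes had, was represented by the brightest one over all arrays.

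Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a model of the 4 groups with sex as an additive term, and p-values were adjusted over all tested transcript clusters by the Benjamini-Hochberg method. A transcript cluster was called at an adjusted p under 0.05. The contrasts were the injury change in each genotype, the genotype difference after each procedure and over both, and the difference between the injury changes of the genotypes. Differences by sex in the injury change or the genotype difference came from a model with a separate mean for each sex in each group. Gene lists were tested with limma's camera at a preset correlation of 0.01, repeated with the correlation estimated from the data and with fry, over lists with at least 5 measured genes, and p-values were adjusted over the lists of a comparison. Positive log2 changes mean higher after injury or higher in knockout. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

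The groups, tests, gene lists and most alternatives were fixed before the data were examined, as was the rule for naming genes. That rule took the 10 genes that rose most and the 10 that fell most among called genes, up to 2 members of each list per direction, the 5 smallest p-values where nothing was called, and Rbm5, Rbm6, Rbm10, Casp2, Fas and Cflar in genotype comparisons. Predicted or unnamed gene models and small RNAs were not named under it. The transcript cluster of Rbm10 listed more than 1 gene, so no value is given for it. The 126 genes followed through every alternative were picked from those the rule named, after their values in the main model were seen and before any alternative was run. A shorter set drawn up later, once the values without single arrays had been seen, was discarded because it left out most of the calls that rested on 1 array, and every count of named genes refers to the full set. Other transcript clusters of the named genes had the same call as the one reported.

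The numbers in the sample titles fall into runs of 1 to 24 and 25 to 42, each with all 4 groups. The labels do not call these runs batches, and each was also fitted alone and as a covariate. Alternatives tried were no sex term, the run as a covariate, only the arrays compared, filters on brightness and on annotation, quantile normalization, centring on array medians, a variance trend, array quality weights, stricter thresholds and leaving out each array in turn. The fits within each run, and those without the 7 arrays with high striatum or choroid plexus marker signal, were chosen after seeing the data. The 7 were WT sham replicate 25, WT CCI replicates 13, 14, 16 and 35 and KO CCI replicates 22 and 40. Leaving them out thus removed more injured wild type than injured knockout arrays. The model was tested on simulated data with independent errors and 200 changed transcript clusters per comparison. At a log2 change of 0.5 it recovered 76.1% for injury in wild type, 73.1% for genotype after sham, 83.6% for genotype after injury and 62.7% for the difference between the injury changes. At a log2 change of 0.25 the last of these was 4.48%. Array values carry no depth, and the number of arrays limits the precision. The limma p-values set each difference against the spread between these animals. The camera p-values at the preset correlation treat the genes of a list as nearly independent, and so depend on the number of genes.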

Results

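The data comprised 28 arrays of mouse cortical tissue taken 48 h after sham anaesthesia or controlled cortical impact, a mechanical brain injury, in wild type mice and in mice labelled as knockout for Rbm5, which encodes an RNA-binding protein that regulates splicing. Each of the 4 groups held 7 animals aged 12 to 15 weeks. Males numbered 3 in WT sham, WT CCI and KO CCI and 4 in KO sham, and Xist and the Y-linked genes matched the label of sex on 28 of 28 arrays. Values are log2 signal with SD or SE and n = 7 per group.

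Rbm5 itself was measured first, as a check of the genotype labels. Its log2 signal was 10.78 ± 0.042 (SD) in WT sham, 10.66 ± 0.063 in WT CCI, 9.76 ± 0.065 in KO sham and 9.75 ± 0.038 in KO CCI, and each of the 14 knockout arrays lay below each wild type array. Over both conditions Rbm5 fell by 0.97 on the log2 scale in knockout (SE 0.027, 1.95-fold, limma adjusted p = 2.4e-19). Probes outside a deleted part of the gene can still give signal, so the remaining level is no measure of residual protein. With injury, Rbm5 in wild type fell by 0.12 (SE 0.038, adjusted p = 0.0348), a call that was lost without any of WT sham replicates 1, 2, 3, 4 and 27 or WT CCI replicates 13, 16, 34, 35 and 36 (adjusted p up to 0.0742). In knockout its log2 change was -0.012 (adjusted p = 0.894).

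**Figure D1:**
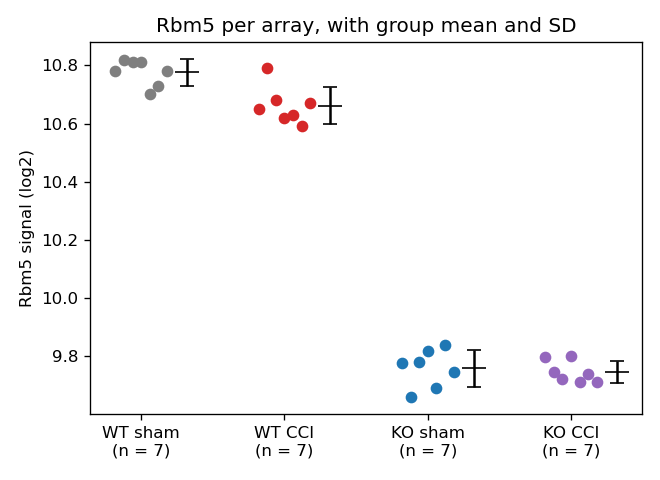
Rbm5 log2 signal of each array by group (points, 7 per group), with the group mean and SD beside them. The knockout arrays lie between 9.66 and 9.84 and the wild type arrays between 10.59 and 10.82.

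The effect of the injury in wild type cortex was asked first. Sham animals had anaesthesia alone, so every injury change includes the craniotomy and the impact, which cannot be told apart. Serpina3n, a protease inhibitor made by reactive astrocytes, rose 142-fold (log2 change 7.15, SE 0.34, adjusted p = 1.76e-14), and Lilrb4a, an inhibitory receptor of myeloid cells, rose 38.9-fold (SE 0.17 on the log2 scale, adjusted p = 1.64e-17). Hmox1, the inducible haem oxygenase, rose 35.9-fold, Ccl12, a chemokine that attracts monocytes, 24.3-fold, and Gfap, the astrocyte intermediate filament, 23.4-fold. Vim rose 19.7-fold, Ly86 17.1-fold, Ifi30 15-fold, A2m 13.9-fold and Lcn2 13.3-fold. Of these, Lilrb4a, Hmox1 and Ccl12 had mean log2 signals of 5.66, 5.61 and 4.86 after sham, below the lowest array median of 5.79. That signal was not shown to be above background, so their folds are not exact. The same held for S100a8, Mki67, Top2a, H2-DMb1, Atf3 and Cd8a, named below. The falls were smaller. Lamp5, a marker of upper-layer neurons and interneurons, fell by 1.48 on the log2 scale (SE 0.11), Kcnv1, a potassium channel subunit, fell by 1.45 (SE 0.15), and the activity-dependent transcription factors Nr4a1 and Npas4 fell by 1.46 (SE 0.34) and fell by 1.41 (SE 0.28). Npy1r, Car10, Cckbr, Trhde and Pcsk1 had log2 changes of -1.14, -1.13, -1.06, -1.06 and -1.05. Ogn, an extracellular matrix protein, fell by 1.06 (adjusted p = 0.0265), a call lost without any of WT sham replicate 2 or WT CCI replicates 13 and 35 (adjusted p up to 0.0736).

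Many markers of myeloid cells rose in wild type. Of 22 measured genes of phagocytic microglia and macrophages, 20 rose and 2 were not called, 20 rose when adjusted over the list alone, and the median log2 change was 1.3 (camera adjusted p = 3.2e-26, and adjusted p = 0.0068 with an estimated correlation). Cd68, a lysosomal protein of phagocytes, rose 13.4-fold. Of 15 monocyte genes, 14 rose, among them Lyz2 (12.8-fold) and the adhesion receptor Cd44 (3.98-fold), with camera adjusted p = 1.7e-11 and adjusted p = 0.0068 with an estimated correlation. Of 13 homeostatic microglia genes, 9 rose, including Fcrls (11.9-fold) and the colony stimulating factor receptor Csf1r (2.48-fold), and 11 were higher adjusted over the list alone. That list had camera adjusted p = 3.1e-08, and adjusted p = 0.095 with an estimated correlation. Of 15 neutrophil genes, 9 rose, among them S100a8 (5.61-fold) and S100a9 (2.39-fold), with camera adjusted p = 0.0024 and adjusted p = 0.22 with an estimated correlation. Among 13 lymphocyte genes none rose and Cd8a, a T cell co-receptor, fell by 0.24 on the log2 scale, and camera gave adjusted p = 0.32.

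Immune mediators followed. Of 15 complement genes, 12 rose, including C1qb (8.41-fold) and C4b (8.05-fold), with camera adjusted p = 1.7e-13 and adjusted p = 0.004 with an estimated correlation. Of 27 cytokine and chemokine genes, 19 rose, among them Ccl3 (3.03-fold) and Ccl9 (3.17-fold), with camera adjusted p = 1.1e-12 and adjusted p = 0.004 with an estimated correlation. The interferon response list had 20 of 22 genes higher, all 22 adjusted over the list alone, with Ifitm3 8.25-fold, Bst2 2.4-fold and Gbp2 2.29-fold higher. Its camera adjusted p was 1e-12, and adjusted p = 0.11 with an estimated correlation. Of 10 genes of MHC class I presentation 8 rose, among them B2m (1.97-fold) and H2-K1 (1.73-fold), with camera adjusted p = 1.5e-05 and adjusted p = 0.1 with an estimated correlation. Of 8 MHC class II genes 4 rose, among them H2-DMb1 (1.64-fold), with camera adjusted p = 0.0018 and adjusted p = 0.11 with an estimated correlation.

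Many genes of glial activation, proliferation and repair rose as well. Of 23 reactive astrocyte genes, 21 rose, with a median log2 change of 1.4 (camera adjusted p = 3.2e-26, and adjusted p = 0.0035 with an estimated correlation). Of 23 cell cycle genes, 22 rose, among them the proliferation marker Mki67 (10.7-fold) and the topoisomerase Top2a (4.59-fold), with camera adjusted p = 4.5e-24 and adjusted p = 0.022 with an estimated correlation. The extracellular matrix and wound repair list had 19 of 23 genes higher, including Tgfbi (10.9-fold) and Lgals1 (7.64-fold), with camera adjusted p = 6e-19 and adjusted p = 0.0068 with an estimated correlation. Of 17 oxidative stress and metal handling genes 11 rose, among them Gpx1 (3.37-fold), and the transferrin receptor Tfrc fell by 0.73 on the log2 scale, with camera adjusted p = 8e-10 and adjusted p = 0.0068 with an estimated correlation. Of 26 cell death and p53 target genes 18 rose, among them the initiator caspase Casp8 (3.18-fold) and the cell cycle inhibitor Cdkn1a (2.4-fold), and Bcl2, which blocks apoptosis, fell by 0.21, with camera adjusted p = 1.3e-09 and adjusted p = 0.022 with an estimated correlation. Of 16 heat shock and unfolded protein response genes, 7 rose and 2 fell, among the rises Atf3 (1.76-fold) and Ddit3 (1.68-fold), with camera adjusted p = 0.021 and adjusted p = 0.36 with an estimated correlation.

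Many neuronal genes fell in wild type. Of 22 synapse genes, 15 fell and none rose, 17 were lower adjusted over the list alone, and the median log2 change was -0.28 (camera adjusted p = 1.4e-10, and adjusted p = 0.022 with an estimated correlation). The postsynaptic scaffold genes Shank1 and Homer1 fell by 0.80 (SE 0.16) and fell by 0.63 (SE 0.12). Of 16 inhibitory neuron genes 10 fell, among them Erbb4 (log2 change -0.66) and the potassium channel Kcnc2 (-0.62), with camera adjusted p = 6.6e-05 and adjusted p = 0.026 with an estimated correlation. Of 16 excitatory neuron genes 10 fell, among them the layer 4 transcription factor Rorb (-0.76), with camera adjusted p = 2.8e-05 and adjusted p = 0.054 with an estimated correlation. Of 17 clock genes 9 fell, among them the repressor Nr1d1 (-0.66), and 1 rose, with camera adjusted p = 0.0063 and adjusted p = 0.22 with an estimated correlation. Of 16 immediate early genes 5 fell and Jun rose (2.21-fold), and camera gave adjusted p = 0.059.

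Part of the oligodendrocyte and endothelial markers rose in injured wild type tissue. Of 14 oligodendrocyte genes 8 rose, among them Trf, which encodes transferrin (6.52-fold), and the myelin tight junction gene Cldn11 (2.71-fold), with camera adjusted p = 1.7e-05 and adjusted p = 0.26 with an estimated correlation. Of 12 oligodendrocyte precursor genes 4 rose, among them Olig2 (2-fold), with camera adjusted p = 0.04 and adjusted p = 0.26 with an estimated correlation. Of 16 endothelial genes 8 rose and 1 fell, with the junction genes Cdh5 and Pecam1 2.21-fold and 2.02-fold higher, camera adjusted p = 6.1e-05 and adjusted p = 0.13 with an estimated correlation. The lists for homeostatic astrocytes (camera adjusted p = 0.18), mural cells (0.68), fibroblasts (0.63), cholesterol synthesis (0.32), oxidative phosphorylation (0.46), RNA-binding and splicing factors (0.88), chromosome 9 neighbours of Rbm5 (0.11) and sex chromosome genes (0.87) were not called. Members of some nevertheless changed, with Aldh1l1 1.66-fold higher, Slc1a2 lower by a log2 change of -0.37, Dcn 2.06-fold higher, Igf2 at -0.83, Hmgcs1 at -0.39, the splicing regulator Ptbp1 1.89-fold higher, and the neuronal RNA-binding proteins Nova1 and Rbfox3 at -0.61 and -0.39. Cycs fell by 0.19 (adjusted p = 0.0266), a call lost without any of WT sham replicates 25, 26 and 27 or WT CCI replicates 35 and 36 (adjusted p up to 0.0687).

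Markers of neighbouring regions varied between injured arrays. The mean of the striatum list was 6.63 ± 0.12 (SD) in WT sham, 7.10 ± 0.92 in WT CCI, 6.79 ± 0.30 in KO sham and 7.15 ± 0.77 in KO CCI, with no called gene in either injury comparison. The striatum signal was 7.75, 8.11 and 8.32 on WT CCI replicates 13, 16 and 35, and 7.79 and 8.46 on KO CCI replicates 22 and 40. The choroid plexus mean was 7.04 on WT sham replicate 25, 7.18 and 6.56 on WT CCI replicates 14 and 35, and 7.01 on KO CCI replicate 40. The lists for hippocampus and thalamus gave camera adjusted p = 0.72 and 0.68 in wild type.

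In all, limma called 11094 of 65956 transcript clusters for injury in wild type, 5843 higher and 5251 lower, and 6774 of the calls were named genes (4212 higher, 2562 lower). After centring each array on its median the split was 5391 higher and 5610 lower, and in the brighter part of the transcript clusters 5195 and 5444. Changes of at least 2-fold were 504 higher and 45 lower. The count was 5900 within title numbers 1 to 24, 5217 within 25 to 42, 11465 with the run as a covariate and 8997 without the 7 arrays with high striatum or choroid plexus signal. Of the 76 called genes followed through the alternatives, 73 kept their call without any single array. Of the 76, 12 lost their call in title numbers 1 to 24 alone, 8 in 25 to 42 alone and 8 without the 7 arrays.

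**Figure D2:**
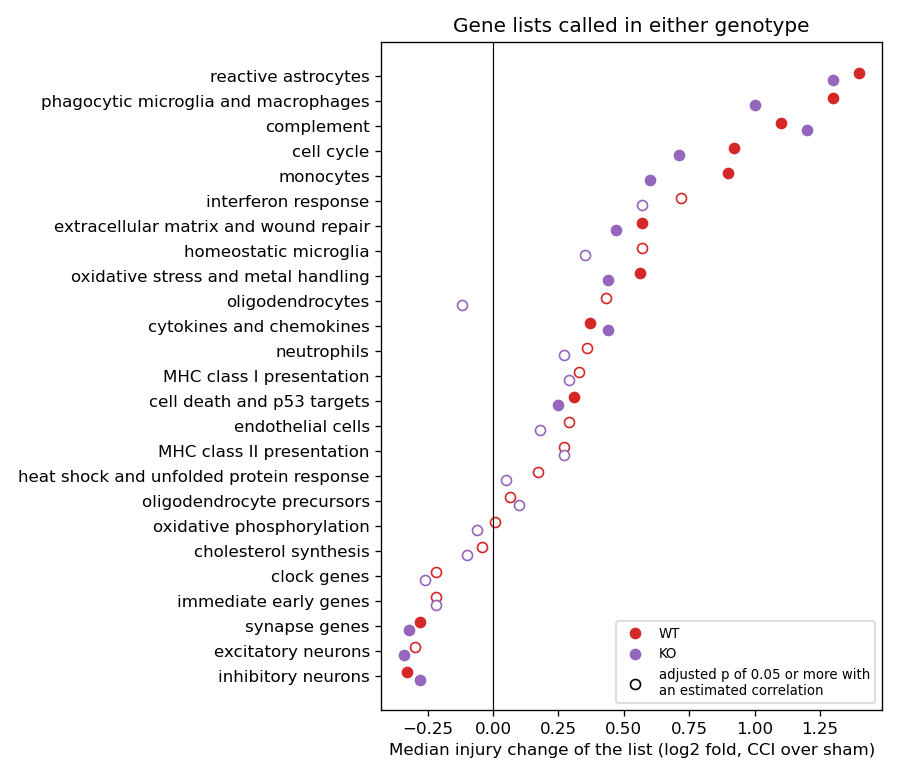
Median log2 injury change (CCI over sham, horizontal axis) of each gene list that camera called in wild type (red) or knockout (purple), where open points have an adjusted p of 0.05 or more with an estimated correlation. Reactive astrocytes and phagocytic microglia and macrophages lie farthest to the right, at 1.4 and 1.3 in wild type.

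The same question was asked in knockout cortex. Serpina3n rose 49.3-fold (log2 change 5.62, SE 0.34, adjusted p = 5.98e-12), Hmox1 33.2-fold, Lilrb4a 30.3-fold, Ccl12 20.2-fold, Lcn2 13.9-fold, Vim 13.1-fold, Lyz2 10.8-fold, Ly86 10.5-fold, A2m 10.1-fold and Gfap 8.32-fold. The sham signals of Hmox1, Lilrb4a and Ccl12 (5.63, 5.71 and 4.91) lay below the lowest array median here too. Kcnv1 fell by 1.45 on the log2 scale (SE 0.15), Npas4 fell by 1.40 (SE 0.28), Lamp5 fell by 1.34 (SE 0.11), Egr3, an activity-dependent transcription factor, fell by 1.21 (SE 0.16), and the potassium channel Kcnh5 fell by 1.13 (SE 0.11). Ptgds, a prostaglandin synthase, fell by 1.07. Nr4a1 fell by 1.17 (adjusted p = 0.0151), a call lost without KO sham replicate 12 (adjusted p = 0.0534). Ogn fell by 1.11 (adjusted p = 0.0196), lost without KO CCI replicate 21 or 40 (up to 0.065), and Bcl2 fell by 0.16 (adjusted p = 0.024), lost without KO sham replicate 31 or KO CCI replicates 21 and 42 (up to 0.0712).

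Gene groups in knockout were as follows. Of 22 genes of phagocytic microglia and macrophages 21 rose, with Cd68 9.99-fold higher (camera adjusted p = 4.4e-24, and adjusted p = 0.0096 with an estimated correlation). Of 23 reactive astrocyte genes 21 rose (5.5e-28, and adjusted p = 0.0017 with an estimated correlation). Of 23 cell cycle genes 22 rose, with Mki67 8.36-fold higher (2e-21, and adjusted p = 0.029 with an estimated correlation). Of 23 extracellular matrix and wound repair genes 20 rose, with Tgfbi 8.89-fold higher (2.3e-17, and adjusted p = 0.0096 with an estimated correlation). Complement had 10 of 15 genes higher, with C1qb 5.88-fold higher (9.3e-13, and adjusted p = 0.0058 with an estimated correlation), and cytokines and chemokines had 20 of 27 higher and 1 lower (2.4e-15, and adjusted p = 0.0017 with an estimated correlation). Of 22 synapse genes 16 fell, with Shank1 and Homer1 at log2 changes of -0.81 and -0.68 (1.1e-13, and adjusted p = 0.0096 with an estimated correlation). Excitatory neuron genes fell in 12 of 16 cases, with Rorb at -0.96 (2.2e-08, and adjusted p = 0.0096 with an estimated correlation), and inhibitory neuron genes in 8 of 16, with Erbb4 at -0.72 (4e-06, and adjusted p = 0.0096 with an estimated correlation).

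Further groups in knockout differed in how the tests fell. Monocyte genes (13 of 15 higher), oxidative stress and metal handling (10 of 17 higher, 1 lower) and cell death and p53 targets (18 of 26 higher, 1 lower) had adjusted p = 0.0096, 0.0096 and 0.043 with an estimated correlation. Interferon response (17 of 22 higher), homeostatic microglia (7 higher and 1 lower of 13), neutrophils (8 of 15 higher), MHC class I (8 of 10 higher) and class II (5 of 8 higher) had camera adjusted p = 4.9e-10, 0.00013, 0.00011, 0.00015 and 0.0012, and adjusted p = 0.17, 0.25, 0.12, 0.16 and 0.11 with an estimated correlation. Endothelial cells (6 higher, 1 lower of 16), immediate early genes (1 higher, 4 lower of 16), clock genes (2 higher, 9 lower of 17), cholesterol synthesis (3 of 16 lower) and oxidative phosphorylation (6 of 23 lower) had camera adjusted p = 0.036, 0.013, 0.00021, 0.0055 and 0.00094, and adjusted p = 0.46, 0.46, 0.11, 0.45 and 0.44 with an estimated correlation. Of 14 oligodendrocyte genes 3 rose, with Trf 4.34-fold and Cldn11 1.59-fold higher, and Aspa, which encodes an enzyme of myelin lipid supply, fell by 0.57, with a median of -0.12, a mean of 0.11 and camera adjusted p = 0.89.

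limma called 11017 transcript clusters in knockout, 5560 higher and 5457 lower, and 6491 named genes (3803 higher, 2688 lower). After centring each array on its median the split was 4021 higher and 7576 lower, and in the brighter part 4740 and 6048. The count was 7509 within title numbers 1 to 24, 2567 within 25 to 42, 11473 with the run as a covariate and 9571 without the 7 arrays with high striatum or choroid plexus signal. Of the 75 called genes followed, 72 kept their call without any single array. Of the 75, 18 lost their call in title numbers 25 to 42 alone, 9 in 1 to 24 alone and 0 without the 7 arrays. Fewer of the 7 belonged to this comparison than to that in wild type, so the losses in the genotypes are not comparable.

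The injury changes of the genotypes were then compared. Across transcript clusters, which are not independent replicates, the changes in wild type and knockout correlated with Pearson r = 0.843 (jackknife SE 0.036 over arrays) and Spearman rho = 0.603. Both comparisons called 7561 transcript clusters, of which 7557 changed in the same direction, against 927 for independent lists. Within title numbers 1 to 24 and 25 to 42 r was 0.738 and 0.688. The test of the difference itself called 0 transcript clusters in limma (smallest adjusted p = 0.198), and 4097 had an unadjusted p under 0.05 against 3298 by chance, so a difference was not detected with these arrays, and simulated differences of 0.25 were recovered in 4.48% of cases. The run as a covariate also gave 0. Among the genes that could be named, the smallest p-values belonged to Shisa3 (difference of log2 changes 0.46, adjusted p = 0.634), Rpl34-ps1 (-0.49, 0.713), Esp3 (0.43, 0.713), Dnm2 (-0.27, 0.713) and Tmc1 (0.26, 0.713). Serpina3n and Gfap had differences of -1.52 (SE 0.48, adjusted p = 0.779) and -1.49 (SE 0.44, adjusted p = 0.744). For Rbm6, Casp2, Fas and Cflar the differences were -0.079, -0.035, -0.28 and -0.038, none called. With only transcript clusters of 1 symbol, or 1 per gene, 1 call appeared, the unnamed gene model 4930548J01Rik, chosen for mention after its value was seen.

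By gene lists, the injury change differed by genotype for 18 lists in camera, 17 of them lower in knockout, and for 0 with an estimated correlation. The 14 oligodendrocyte genes had a median difference of -0.51 (camera adjusted p = 7.2e-15, and adjusted p = 0.44 with an estimated correlation), with 0 called over all transcript clusters and 10 lower adjusted over the list alone. Their mean log2 signal was 10.33 ± 0.20 (SD) in WT sham, 10.98 ± 0.094 in WT CCI, 10.58 ± 0.20 in KO sham and 10.69 ± 0.39 in KO CCI. Endothelial genes had a median of -0.18 and homeostatic microglia genes -0.21, both with camera adjusted p = 0.00014, and adjusted p = 0.44 and 0.59 with an estimated correlation.

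**Figure D3:**
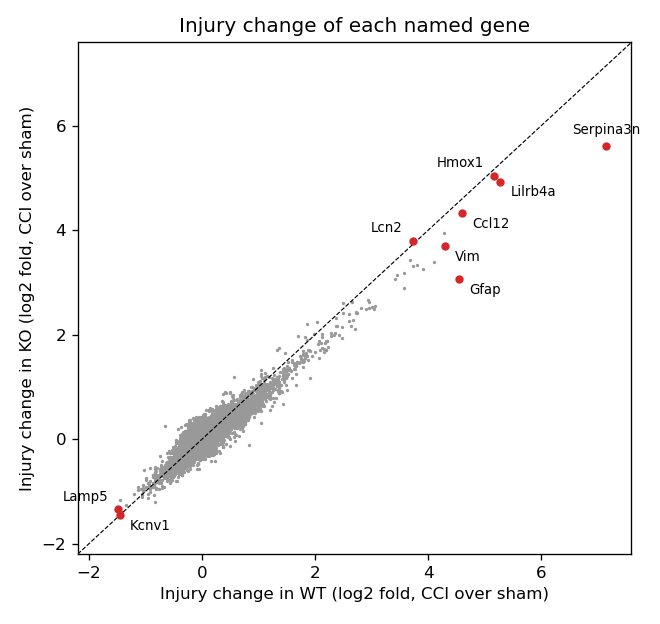
Log2 injury change (CCI over sham) of each named gene in wild type (horizontal axis) and in knockout (vertical axis), with 9 genes marked in red and the dashed line at equal change. Serpina3n lies at 7.15 in wild type and 5.62 in knockout.

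The genotype difference without injury was examined next. In KO sham, Csnka2ip was 2.08-fold higher than in WT sham (log2 difference 1.06, SE 0.11, adjusted p = 1.39e-06), Wdfy1, which takes part in Toll-like receptor signalling, 1.84-fold higher, and Mpi, the mannose phosphate isomerase, 1.55-fold higher. Tgm3 was 1.5-fold, Nvl, a ribosome assembly ATPase, 1.42-fold, Oacyl 1.41-fold and the splicing helicase Dhx15 1.24-fold higher. Akr1b10, an aldo-keto reductase, fell by 0.79 (SE 0.064, adjusted p = 1.8e-08), Zfp972 fell by 0.70, Rasgrf2, a guanine nucleotide exchange factor of neurons, fell by 0.64, and Chrdl1 fell by 0.63. Akap8l, Cfap300 and Hnrnpdl, the last an RNA-binding protein, had log2 differences of -0.51, -0.51 and -0.47. Rbm6, Casp2, Fas and Cflar, fixed in advance as genes of interest, had log2 differences of 0.084, 0.024, 0.11 and 0.075 with adjusted p = 0.337, 0.884, 0.76 and 0.678.

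Of the 25 called genes followed in this comparison, 10 lost their call when 1 array was left out. Serpina3n was 2.67-fold higher in KO sham (log2 difference 1.42, SE 0.34, adjusted p = 0.0356), with a mean of 9.58 ± 1.15 (SD) against 8.14 ± 0.34 in WT sham, and was lost without any of WT sham replicates 1, 2, 3, 25, 26 and 27 or KO sham replicates 9, 11 and 12 (adjusted p up to 0.0892). Gfap was 2.57-fold higher (adjusted p = 0.0263), lost without WT sham replicate 2 or 25 or KO sham replicate 9, 11, 12 or 31 (up to 0.075). Pnck was 1.48-fold higher (adjusted p = 0.0281), lost without WT sham replicate 1, 3, 4, 26 or 27 or KO sham replicate 10, 12 or 33 (up to 0.0777). Postn was 1.26-fold higher (adjusted p = 0.0285), lost without WT sham replicate 1, 2, 4 or 25 or KO sham replicate 9, 11 or 33 (up to 0.0739). Lif, a cytokine, fell by 0.20 (adjusted p = 0.0345), lost without WT sham replicate 2, 3, 4 or 27 or KO sham replicate 9, 10, 11, 12 or 33 (up to 0.093). Gclc, of glutathione synthesis, fell by 0.20 (adjusted p = 0.0218), lost without WT sham replicate 2 or 25 or KO sham replicate 11 (up to 0.0558), and Scn7a fell by 0.58 (adjusted p = 0.023), lost without WT sham replicate 2 or KO sham replicate 12 (up to 0.066). Igfbp5 (1.42-fold higher, adjusted p = 0.0473) was lost without any 1 of 20 arrays (up to 0.146), all but WT sham replicate 2, WT CCI replicates 14 and 35, KO sham replicate 33 and KO CCI replicates 21, 24, 40 and 41. Ntsr2 (1.41-fold higher, adjusted p = 0.0471) was lost without any 1 of 18 arrays (up to 0.13), all but WT sham replicate 1, WT CCI replicates 14, 34 and 35, KO sham replicate 9 and KO CCI replicates 21, 22, 24, 40 and 41. Efcab1 (log2 difference -0.53, adjusted p = 0.0459) was lost without any 1 of 19 arrays (up to 0.125), all but WT sham replicates 3 and 27, WT CCI replicates 13, 35 and 36 and KO CCI replicates 21, 23, 41 and 42.

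Few gene lists stood out among genes differing by genotype after sham. The 14 oligodendrocyte genes had a median of 0.26 with 0 called (camera adjusted p = 0.00026, and adjusted p = 1 with an estimated correlation), 23 oxidative phosphorylation genes had a median of 0.044 with 0 called (0.015, and adjusted p = 1 with an estimated correlation), and of 40 RNA-binding and splicing factors 1 was higher and 3 were higher adjusted over the list alone (0.014, and adjusted p = 1 with an estimated correlation). Of 51 chromosome 9 neighbours of Rbm5, 0 were called in limma in this comparison. In all, limma called 847 transcript clusters, 335 higher and 512 lower, and 565 named genes (201 higher, 364 lower). After centring on array medians the split was 341 higher and 345 lower, and with array quality weights the count was 1279. It was 472 within title numbers 1 to 24, 5 within 25 to 42, 1015 with the run as a covariate and 740 without the 7 arrays with high striatum or choroid plexus signal. Of the 25 called genes followed, 23 lost their call in title numbers 25 to 42 alone, 10 in 1 to 24 alone and 5 without the 7 arrays. Without WT sham replicates 1, 2, 26 or 27 it was 524, 488, 520 and 557, and without KO sham replicates 11 or 12 it was 438 and 447.

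After injury the knockout was compared with the injured wild type. Csnka2ip was 2.06-fold higher (log2 difference 1.04, SE 0.11, adjusted p = 1.88e-06), Wdfy1 1.67-fold, Pnck, a neuronal calmodulin-dependent kinase, 1.58-fold, Mpi 1.49-fold and Nvl 1.42-fold higher. Pinx1, a telomerase inhibitor, was 1.32-fold, Ints6l and Tgm3 1.31-fold, Scaper 1.29-fold and Dhx15 1.22-fold higher. Akr1b10 fell by 0.77 (SE 0.063, adjusted p = 2.95e-08), Zfp972 fell by 0.63, Chrdl1 fell by 0.57, Vamp1, a synaptic vesicle protein, fell by 0.57, and Rasgrf2 fell by 0.54. Hnrnpdl and Akap8l had log2 differences of -0.50 and -0.50, and Rbm5 fell by 0.91. Serpina3n and Gfap had log2 differences of -0.11 (adjusted p = 0.959) and -0.13 (adjusted p = 0.941). Rbm6, Casp2, Fas and Cflar had log2 differences of 0.0052, -0.011, -0.16 and 0.036 with adjusted p = 0.982, 0.961, 0.646 and 0.889.

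Among endothelial and oligodendrocyte genes, 2 and 1 were called lower in injured knockout tissue. Of 16 endothelial genes 2 fell, 9 were lower adjusted over the list alone, and the median was -0.24 (camera adjusted p = 5.8e-10, and adjusted p = 0.15 with an estimated correlation). Of 12 mural cell genes 0 were called in limma, and the median was -0.11 (camera adjusted p = 0.00083, and adjusted p = 0.24 with an estimated correlation). Cdh5 fell by 0.49 (adjusted p = 0.0197), a call lost without WT CCI replicate 15 (adjusted p = 0.0522), and Pecam1 fell by 0.34 (adjusted p = 0.0228), lost without WT CCI replicate 15 or KO CCI replicate 21 or 41 (up to 0.0574). Of 14 oligodendrocyte genes 1 fell, 3 were lower adjusted over the list alone, and the median was -0.29 (camera adjusted p = 1.2e-06, and adjusted p = 0.66 with an estimated correlation). The gene was Mbp, the myelin basic protein, which fell by 0.42 (adjusted p = 0.049), and its call was lost without any 1 of 25 of the 28 arrays, all but WT sham replicate 25, KO sham replicate 12 and KO CCI replicate 42 (up to 0.121). Cyp4f15 was 1.29-fold higher (adjusted p = 0.0204), lost without WT CCI replicate 34 or KO CCI replicate 23 or 41 (up to 0.0552), and Kcnab3 fell by 0.59 (adjusted p = 0.0283), lost without WT CCI replicate 13 or 14 or KO CCI replicate 22, 40 or 41 (up to 0.0806). Camera called 11 lists, all lower, and 0 with an estimated correlation. limma called 431 transcript clusters, 149 higher and 282 lower, and 259 named genes (80 higher, 179 lower). The split after centring was 89 higher and 331 lower. With only the injured arrays in the model the count was 131, within title numbers 1 to 24 and 25 to 42 it was 125 and 15, with the run as a covariate 481, and without the 7 arrays with high striatum or choroid plexus signal 187, of which 113 were shared. Of the 23 called genes followed, 21 lost their call in title numbers 25 to 42 alone, 12 in 1 to 24 alone and 10 without the 7 arrays. The 7 held more injured wild type than injured knockout arrays.

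Genotype differences over both conditions used all arrays. The genotype differences after sham and after injury correlated with r = 0.29 and rho = 0.175 across transcript clusters, and 243 were called in both, each in the same direction, against 2.95 for independent lists. Csnka2ip was 2.07-fold higher (SE 0.077 on the log2 scale, adjusted p = 7.03e-10), Wdfy1 1.75-fold, Pnck 1.53-fold, Mpi 1.52-fold, Nvl 1.42-fold, Tgm3 1.4-fold, Itih3 1.39-fold, Sfrp1, an inhibitor of Wnt signalling, 1.38-fold, Oacyl 1.34-fold and Akr1c18 1.33-fold higher. Akr1b10, Zfp972, Chrdl1, Rasgrf2, Kcnab3 and Scn7a had log2 differences of -0.78, -0.67, -0.60, -0.59, -0.53 and -0.53. Akap8l and Hnrnpdl had log2 differences of -0.50 and -0.48. Rbm6, Casp2, Fas and Cflar had log2 differences of 0.045, 0.0064, -0.024 and 0.055, none called. Of 16 excitatory neuron genes 2 rose, Neurod6 (1.27-fold) and Fezf2 (1.25-fold), and 1 fell, Rasgrf2 (camera adjusted p = 0.53). Of 16 inhibitory neuron genes Npy rose (1.22-fold) and Kcnc2 fell by 0.29 (camera adjusted p = 0.87), and of 22 synapse genes 1 rose, the glutamate receptor subunit Gria2 (1.12-fold, camera adjusted p = 0.88). Of 40 RNA-binding and splicing factors 4 rose and 1 fell (camera adjusted p = 0.11), among them Dhx15 (1.23-fold) and Nova1 (log2 difference -0.22). Srsf6 was 1.11-fold higher (adjusted p = 0.0337), a call lost without WT sham replicate 25, 26 or 27, WT CCI replicate 34, KO sham replicate 10, 11 or 12 or KO CCI replicate 22, 24 or 42 (up to 0.0677). Gfap was not called (log2 difference 0.62, adjusted p = 0.17), except when KO sham replicate 33 was left out (log2 difference 0.75).

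Further called genes in this comparison were few in each list. Of 16 endothelial genes 3 fell and 9 were lower adjusted over the list alone, with Cdh5 and Pecam1 at -0.32 and -0.21 (camera adjusted p = 9.3e-06, and adjusted p = 0.84 with an estimated correlation). Of 16 cholesterol synthesis genes 1 fell, Idi1 at -0.22, and 5 were lower adjusted over the list alone (camera adjusted p = 0.00033, and adjusted p = 0.99 with an estimated correlation). Ntsr2 was 1.31-fold and Postn 1.2-fold higher, and Gclc, Ccng1 and Col4a2 had log2 differences of -0.19, -0.21 and -0.12. Of the named neighbours of Rbm5 on chromosome 9, 0 of 51 were called by limma. limma called 2081 transcript clusters, 897 higher and 1184 lower, and 1339 named genes (536 higher, 803 lower). After quantile normalization the split was 1015 higher and 1039 lower, and after centring on array medians 737 and 1134. The count was 872 within title numbers 1 to 24, 74 within 25 to 42, 2205 with the run as a covariate and 961 without the 7 arrays with high striatum or choroid plexus signal. Of the 35 called genes followed, 26 lost their call in title numbers 25 to 42 alone, with 3 arrays per group, 15 in 1 to 24 alone and 9 without the 7 arrays.

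Short noncoding RNAs were prominent among the genotype calls. Of 311 small nucleolar RNA transcript clusters with a mean log2 signal of at least 8, 201 were lower in knockout over both conditions and 0 higher in limma (median log2 difference -0.17), and of 348 small nuclear RNA transcript clusters 187 were lower and 0 higher (median -0.24). After quantile normalization 141 and 159 were lower, with medians of -0.12 and -0.20, and after centring on array medians 202 and 191 were lower. On chromosome 7, 169 of 179 small nucleolar RNA transcript clusters were lower (median -0.24), against 32 of 132 on other chromosomes (median -0.067). Called small nucleolar RNAs on chromosome 7 formed 147 neighbouring pairs, whose correlation within groups had a median of 0.86. These transcript clusters are therefore not independent, and the counts are no measure of how many separate RNAs changed. Of all 963 small nucleolar and 926 small nuclear RNA transcript clusters, 118 and 106 were called lower after sham, but 49 and 1 after injury. Those with a signal of at least 8 had medians of -0.20 and -0.30 after sham and of -0.17 and -0.17 after injury, and 0 were called for a difference between the injury changes in limma. The mean small nuclear RNA signal of the injured groups overlapped, at 12.74 to 13.10 in KO CCI and 12.75 to 13.16 in WT CCI, and so did that of the sham groups, at 12.21 to 12.72 in KO sham and 12.60 to 12.83 in WT sham. The small nucleolar RNA mean of KO sham replicate 32 (14.12) also lay above those of WT sham replicates 1 and 2 (14.11 each). After injury, that of KO CCI replicate 42 (14.16) lay above those of WT CCI replicates 15 and 34 (14.13 each). These classes were singled out after their values were seen.

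**Figure D4:**
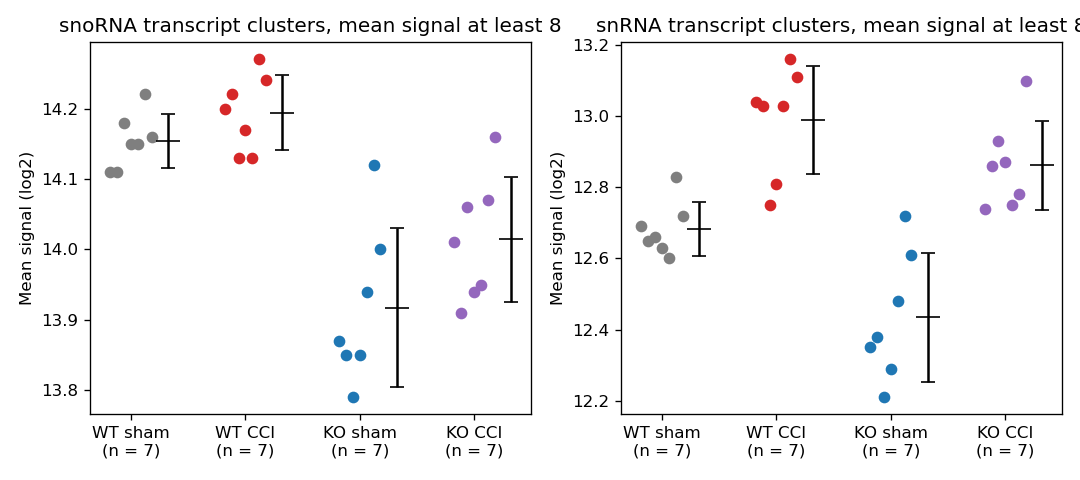
Mean log2 signal of each array (points, 7 per group) over small nucleolar RNA (left) and small nuclear RNA (right) transcript clusters with a mean signal of at least 8, with the group mean and SD beside them. Over both conditions the median log2 differences between genotypes were -0.17 and -0.24.

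Whether genes existed whose injury change differed by sex was tested in a model with separate means for each sex. The injury change differed by sex for 7 transcript clusters in limma (1 with the higher change in females), and 4058 had an unadjusted p under 0.05 against 3298 by chance. Of these, 6 lie on the Y chromosome, and 5 list the multicopy Y-linked genes Gm20854 and Orly, named here after their values were seen. A transcript cluster of Gm20854 changed by 0.032 in females and 1.2 in males (difference -1.17, SE 0.14, adjusted p = 0.000942), and 1 of Orly by -0.011 and 0.76 (difference -0.77, adjusted p = 0.00445). A transcript cluster without a listed gene on chromosome 18 changed by 0.0015 in females and -0.64 in males. Fits within title numbers 25 to 42, or without the 7 arrays with high striatum or choroid plexus signal, left 1 injured male per genotype. Their counts therefore rest on single injured males, and are listed only among the processing alternatives, not as evidence. The count was 0 within title numbers 1 to 24 and 12 with the run as a covariate. It was 4 without WT sham replicate 25 or KO sham replicate 33, 15 without WT CCI replicate 13, 80 without WT CCI replicate 14, 177 without KO CCI replicate 22 and 11 without KO CCI replicate 23. The genotype difference by sex gave 0 calls in limma (smallest adjusted p = 0.868, with 3693 at an unadjusted p under 0.05), and 1 without KO CCI replicate 21.

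**Figure D5:**
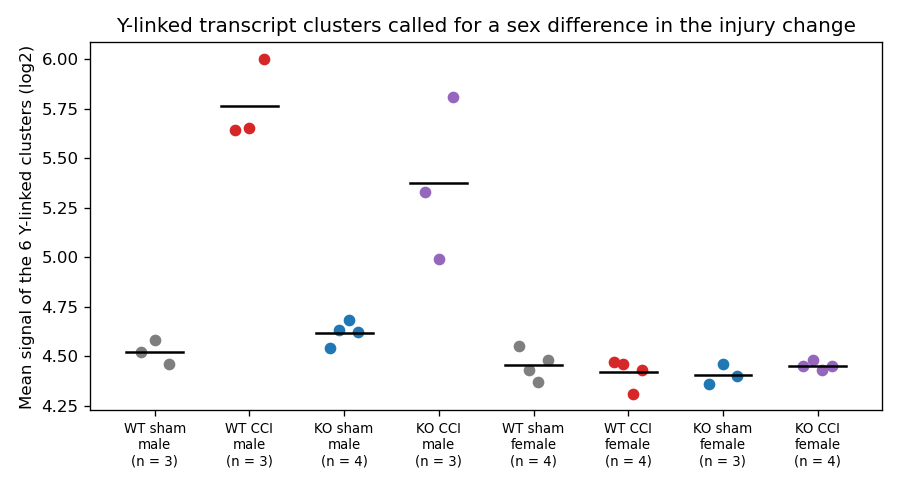
Mean log2 signal of each array over the 6 Y-linked transcript clusters called for a sex difference in the injury change, by group and sex, with lines at the means. The 6 injured males lie between 4.99 and 6.00 and the 7 sham males between 4.46 and 4.68.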

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

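The tests of recovery, of flanking DNA, of random placement, of other transcripts and of single male arrays were chosen after the results were seen, and the tests of regrouped arrays, runs, host genes, shared probes and genomic DNA were written before their values were seen.

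Arrays were regrouped at random into groups of the same sizes, 100 splits with the real one. The real count was the only one as large (1 of 100 splits) for injury in wild type (11094, highest other 3346) and in knockout (11017, 5843). The same held for genotype after sham (847, 253), after injury (431, 14) and over both conditions (2081, 2). Random regrouping thus rarely gave such counts, but 100 splits cannot show a share below 1 in 100. The regrouping kept the group sizes but not the balance of sex and title numbers. The sex difference in the injury change was also the only one as large (1 of 100 splits), but by a small margin (7, 4). It fell to 4 without WT sham replicate 25 and to 0 within title numbers 1 to 24, so that count rests on few calls. For the difference of injury changes by genotype and of genotype differences by sex, limma called 0, and 100 of 100 splits gave as many (highest other 268 and 6, with 4097 and 3693 at an unadjusted p under 0.05). A split with 268 calls may reflect a structure of the samples, which was not tested. These splits kept sham and injured arrays apart and exchanged genotypes, so the genotype differences themselves are not excluded as its source. Chance cannot be excluded for the numbers of lists that camera called. As many lists came in 8 splits for injury in wild type (22, highest other 24), 16 for injury in knockout (22, 26), 58 for genotype after sham (3, 13), 48 for genotype after injury (11, 22), 97 for genotype over both conditions (2, 19) and 8 for the difference of injury changes (18, 26). The other splits had medians of 12, 15, 3, 10, 9 and 9 lists in the same order. Camera at the preset correlation of 0.01 thus often called lists without the real grouping. Its adjusted p-values at that setting are therefore no evidence on their own. The estimated correlations ranged from 0.01 for hippocampus to 0.85 for striatum. How much of this comes from correlated genes or from a structure of the samples was not tested.

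Small nucleolar and small nuclear RNA transcript clusters with a mean signal of at least 8 were lower in knockout over both conditions, with a median log2 difference of -0.22. Lower recovery of all small RNA in knockout samples, microRNA included, is argued against by microRNA transcript clusters, whose median was -0.007. The 88 ribosomal RNA transcript clusters with such a signal had a median of -0.16 with 0 called, near that of small nucleolar RNA (-0.17). A lower recovery that spares microRNA therefore stays open. The run of title numbers is argued against by medians of -0.16 and -0.26 within the runs. A lower level of the host genes stays open. The median of 9 host genes was -0.033, with an approximate SE of that median of 0.048. Single host genes ranged from -0.23 (Snhg14) to 0.073 (Snhg9). The host genes with a mean signal of at least 8 were Snhg14, Snhg5 and Snhg11, with differences of -0.23, -0.20 and -0.19. Snhg14 and Snhg5 were called lower, and Snhg11 was not called. The other host genes were dimmer, so the median over all 9 cannot decide this. The host gene test first used only bright host genes and was changed to all 9, as its prediction was worded, after the first value was seen. A biological effect of Rbm5 loss on these RNAs may also account for the pattern, and was not tested.

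Genotype calls lay in neighbouring transcript clusters more often than random placement gave, with 443 neighbouring pairs against at most 86 in 99 random placements (1 of 100, the real one included). Chromosome 7, with 6.86% of its transcript clusters called against 3.16% of all, held 207 of these pairs, 147 of them between small nucleolar RNAs, and chromosome 2, with 3.91% called, held 69. Of the 51 named neighbours of Rbm5, 0% were called, against 4.38% of all named genes, so no excess of calls was seen there. At that rate few calls would come from so small a set. The test therefore cannot decide whether DNA from another strain lies around Rbm5. Chromosome 9 had 3.58% of its transcript clusters called. Probes shared between neighbouring transcript clusters could account for part of it, since the within-group correlation of such pairs had a median of 0.63, against 0.034 for random called pairs, and 57 pairs were identical on all arrays, but the median was 0.86 for the small nucleolar RNA pairs on chromosome 7 and 0.38 for the other 296 pairs. Local co-regulation and strain differences elsewhere in the genome, including chromosome 2, where 8 of the 10 unnamed transcript clusters with the smallest p-values lay (log2 differences of -1.07 to -0.66), stay open and were not tested.

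Y-linked transcript clusters were higher in injured males. Cross-hybridization of other transcripts that injury raises is argued against by the 552 Y-linked transcript clusters not called for the sex difference, whose mean changed by 0.058 (SE 0.070) in females and 0.50 (SE 0.075) in males, with the female change below 0.5 of the male change by 0.19 (SE 0.080). A single injured male array is argued against by the same mean, in which 6 of 6 injured males lay above every sham male. Genomic DNA in the RNA of injured samples is a candidate explanation: 11 sets of at least 5 identical dim transcript clusters off the Y chromosome had a median injury change of 0.37, and 10 of the 11 sets rose in both sexes. Expression of these genes in injured male tissue stays open and was not tested.

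Sex differences in the injury change, by the test of the difference, were -1.17 and -1.32 for the transcript clusters of Gm20854, -0.77, -0.70 and -0.70 for those of Orly, -1.34 for a Y-linked transcript cluster and 0.64 for 1 on chromosome 18, both without a listed gene. Differences of the injury change by genotype, by camera, had list medians of -0.51 for oligodendrocytes, -0.21 for homeostatic microglia, -0.18 for endothelial cells, -0.17 for phagocytic microglia and macrophages, -0.16 for cell cycle, -0.16 for mural cells, -0.11 for extracellular matrix and wound repair and -0.10 for complement. Smaller medians were -0.091 for interferon response, -0.085 for homeostatic astrocytes, -0.084 for cholesterol synthesis, -0.081 for oligodendrocyte precursors, -0.079 for oxidative phosphorylation, -0.070 for oxidative stress and metal handling, -0.035 for cell death and p53 targets, -0.034 for chromosome 9 neighbours of Rbm5, -0.023 for RNA-binding and splicing factors and 0.069 for lymphocytes. With an estimated correlation 0 of these lists were called.

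Single arrays stood far from the other 6 of their group in 30 of 504 pairs of a followed gene and a group, where chance gives about 1 in 20 groups, or 25. The gap to the nearest array, as a share of the range, was 0.93 for Ifi30 in WT sham (low on replicate 3), 0.825 for Gbp2 in KO CCI (high on replicate 23), and 0.82 for S100a9 and 0.792 for S100a8 in WT sham (both high on replicate 2). In WT sham it was also 0.724 for Homer1, 0.60 for Casp8, 0.599 for Rbm6, 0.59 for Col4a2, 0.586 for Ddit3, 0.583 for Sfrp1 and 0.573 for Dnm2. In WT CCI it was 0.629 for Shank1, 0.599 for Gbp2 and 0.593 for Top2a. In KO sham it was 0.65 for Oacyl, 0.644 for Idi1, 0.62 for Vamp1, 0.614 for Efcab1, 0.604 for Ddit3, 0.591 for Nvl, 0.583 for Ccl12, 0.58 for Akr1c18 and 0.57 for Rorb. In KO CCI it was 0.694 for Idi1, 0.667 for Shisa3, 0.641 for Kcnh5, 0.617 for Cd44, 0.607 for Chrdl1, 0.58 for Csnka2ip and 0.57 for S100a8. WT sham replicate 25 was the array in 4 of these pairs.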

How the results depend on the processing

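The fits within each run of title numbers, and those without the 7 arrays with high striatum or choroid plexus signal, were chosen after the results were seen, as was the correlation of injury changes with transcript clusters of 1 symbol.

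Counts in order are for injury in wild type, injury in knockout, genotype after sham, genotype after injury and genotype over both conditions. They were 2134, 1826, 114, 71 and 86 at 1.5-fold or more and 7268, 7060, 278, 181 and 1006 at an adjusted p under 0.01, where the stricter threshold itself lowers them. Within title numbers 25 to 42, with fewer arrays, they were 5217, 2567, 5, 15 and 74, and within 1 to 24 they were 5900, 7509, 472, 125 and 872. Genotype after injury gave 131 with only the arrays compared and 187 without the 7 arrays, where genotype over both conditions gave 961, and genotype after sham gave 1279 with array quality weights. The sex difference in the injury change gave 12 with the run as a covariate, 1 in the brighter part, 0 with 1 transcript cluster per gene, 15 after quantile normalization, 15 after centring, 4 at an adjusted p under 0.01, 0 and 43 within the runs and 115 without the 7 arrays. For the sex difference, the fits within title numbers 25 to 42 and without the 7 arrays left 1 injured male per genotype. Their counts are therefore no evidence of more sex differences. The difference of injury changes by genotype gave 1 with transcript clusters of 1 symbol and 1 with 1 per gene, where fewer were tested. The correlation of injury changes was 0.905 in the brighter part, 0.894 with 1 symbol, 0.894 with 1 per gene, 0.738 and 0.688 within the runs and 0.798 without the 7 arrays. Lists called with an estimated correlation were 11 and 12 for injury, and 0 for genotype after sham, after injury, over both conditions and for the difference of injury changes. With fry the last 4 were 0, 2, 1 and 0, and in the brighter part lists numbered 1 after sham, 4 after injury and 3 for the difference of injury changes. Beyond the thresholds and the smaller numbers of arrays and tests, the cause was not tested.

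Without 1 array the counts ranged from 9616 to 11265 for injury in wild type, 9268 to 11406 for injury in knockout, 438 to 921 for genotype after sham, 298 to 508 for genotype after injury, 1789 to 2090 for genotype over both conditions, 0 to 0 for the difference of injury changes by genotype, 4 to 177 for that by sex and 0 to 1 for genotype by sex. The Rbm5 difference ranged from -0.97 to -0.95 and the correlation from 0.821 to 0.851. Of the values of followed genes without 1 array, 101 of 812 lost their call for genotype after sham, 37 of 812 after injury, 10 of 1148 over both conditions, and 18 and 6 of 2156 for injury in wild type and knockout. No call of a followed gene reversed. The balance of higher and lower injury calls turned to more lower ones in wild type (5391 higher, 5610 lower) and knockout (4021, 7576) after centring and in the brighter part (5195, 5444 and 4740, 6048). In knockout it turned also after quantile normalization (5236, 5350) and at or above the 25th percentile of brightness (5694, 5856). Every count not given above stayed within 1.5 times the reported one. For genotype over both conditions and the difference of injury changes, the arrays compared are all 28, so that alternative gave no value. No paired analysis was possible because the groups share no title numbers. Arrays give signal over background and no depth, which limits dim transcripts.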

Other observations

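Other transcript classes moved with injury in both genotypes, and were looked at after the results were seen. Of 348 small nuclear RNA transcript clusters with a mean signal of at least 8, limma called 222 higher and 1 lower in wild type and 300 higher and 1 lower in knockout, with median log2 changes of 0.28 and 0.45. After quantile normalization 135 and 309 were higher, with medians of 0.20 and 0.37. Of 88 ribosomal RNA transcript clusters 80 were higher in wild type and 40 in knockout (medians 0.66 and 0.63), against 17 and 13 after quantile normalization (medians 0.54 and 0.55) and 75 and 8 after centring on array medians (medians 0.65 and 0.59), so the changes stayed about as large while fewer were called. Pseudogenes were called higher in 925 cases and lower in 114 in wild type, and in 864 and 102 in knockout.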
